A study of Raphidocelis subcapitata with 270 samples.

How the data were processed

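The deposited values are raw counts per gene in 270 libraries, in one table for each of the 12 chemicals. Per the labels' protocols, algae in exponential growth were loaded into 96-well plates, dosed, and kept for 24 h at 24 °C under constant light of 4300 lux with intermittent shaking. Total RNA was then extracted and libraries were made with a 3′ mRNA kit with unique molecular identifiers. Per the submitters' processing notes, fastp 0.23.2, STAR 2.7.10a, SAMtools 1.15.1 and featureCounts 2.0.6 were used before the counts were deposited. The genome build, the annotation, the strand setting and whether reads were collapsed by their molecular identifiers are not given in the sources used here. If they were not collapsed, counts include PCR copies, and counting intervals are then too narrow. Counting by 3′ tags makes counts nearly independent of transcript length, and genes with near-identical copies or overlapping ends could share or lose reads in a way that the tables do not show.

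The tables hold 13429 genes by identifier, with 24 columns each, and every column was matched to a sample by its name. Each set of 3 DMSO libraries appears in the tables of both of its chemicals. The counts were identical in the 2 tables except in replicate C of 2 sets, where 1 gene differed by 1 count. Library totals ran from 596651 to 1909938. All 288 pairs of libraries within a group, each DMSO pair counted in the tables of both its chemicals, differed by more than sampling noise. Chi-square values per degree of freedom ran from 1.62 to 9.70, so no library was treated as a duplicate. No genome or gene table was used here and the files do not pair the identifiers with names. For that reason the 28 gene lists fixed in advance (photosynthesis, pigment synthesis, stress responses and others) could not be tested, none of their results is reported, and no check of GC content or gene length was possible.

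Each chemical was analysed on its 24 libraries, 8 groups of 3, with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default settings, libraries were scaled by TMM, and a quasi-likelihood model with one coefficient per level (glmQLFit) was tested over all 7 levels at once and for each level against DMSO (glmQLFTest). P-values were adjusted by Benjamini and Hochberg within each test, and genes with an adjusted p under 0.05 are called. A standard error on the log2 scale is the absolute log2 fold change divided by the square root of the F statistic. CPM values use the TMM-scaled library totals. Both chemicals of a control set were also fitted together and tested directly against each other at each level. That test compares treated libraries only, while the DMSO libraries stay in the fit and so enter the filter, the scaling and the estimate of the spread. The design with no block for the replicate letter, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The comparisons by place in the label and of recurrent genes in a left-out control set, the direct tests between the chemicals of a control set, the counts of genes recurring across control sets, the test with DMSO left out, the single-library exclusions of treated libraries and all exclusions for recurrent genes and genes called at 6 or more levels were added after.

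The fullest level of a chemical is the one with the most calls. Because no gene names were given, the rule named the 2 identifiers with the largest rise and the 2 with the largest fall at that level, among genes called both there and over all levels, with a mean of at least 10 counts per library and all 3 treated libraries on the same side of all 3 DMSO libraries. This yielded 48 gene and chemical combinations.

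The test was checked on simulated counts drawn from the means, totals and dispersions of each chemical's libraries with 200 genes changed at D1. In the simulation of gabapentin, with 9101 genes tested, edgeR recovered 18.5% of genes changed by 1.5-fold, 63.6% of those changed by 2-fold and 87.7% of those changed by 4-fold at D1, with 4 false calls there. For fexofenadine, with 9423 genes tested, the shares were 30.8%, 71.6% and 89.4% with 15 false calls. Depth and the 3 libraries per group thus leave many changes of 1.5-fold uncalled.

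Alternatives were DESeq2 1.42.0 (likelihood ratio and Wald tests), RLE scaling, no filter on low counts, a filter at a mean of 10 counts, the replicate letter as a block, a slope over the level numbers, one fit for both chemicals of a control set, adjustment over all 12 chemicals together, and leaving out each replicate or DMSO library. Overlaps of calls were computed at the fullest level for chemicals with 50 or more calls. For the 5 pairs with shared DMSO libraries, 20 simulations of unchanged groups were drawn, with log2 CPM values at a prior count of 2. Recurrence across control sets was compared with 1000 random draws, plain and matched on mean expression in 10 bins.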

Results

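Gene expression was measured in Raphidocelis subcapitata, a unicellular freshwater green alga used in toxicity testing, after 24 h of exposure in 96-well plates to each of 12 chemicals or to the solvent dimethyl sulfoxide (DMSO). Poly(A) RNA was counted by 3′ tag sequencing, which reads the end of each transcript. Each chemical had 7 labelled dose levels, D1 to D7, with 3 libraries per level, and the 12 chemicals fell into 6 control sets in which a pair of chemicals shared 3 DMSO libraries. The 270 libraries held between 596651 and 1909938 counts, with a median of 1083755, over 13429 genes. The series text describes half-log dilutions, typically from 66.7 to 0.021 µM, a range that spans 8 half-log concentrations, while 7 levels are labelled. The labels do not give the concentration of a level or say which end of the series was D1, so the levels are treated below as named groups without an order. The labels also do not say whether the 3 libraries of a group were separate cultures, so the p-values measure the spread between these libraries, which may be partly technical. The files give gene identifiers without names, and each gene below is therefore named by its identifier only.

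The comparison with DMSO asked which genes differed in each chemical and at which level. D1 was the level with the most genes called in 10 of the 12 chemicals, the exceptions being 4-chlorophenyl methyl sulfone, with the most at D6, and cis-nonachlordane, with the most at D2. Without DMSO replicate B fexofenadine had 1 gene called at D1 and 1 at D5. cis-nonachlordane had the most at D1 without DMSO replicate A and at D7 without B or C. The number called at the fullest level ran from 40 for fexofenadine to 1728 for 2-tert-butyl-4-methoxyphenol, while the test over all levels gave 1081 genes for gabapentin and 951 for 2-tert-butyl-4-methoxyphenol. The chemical listed second in the labels had more genes called than the first in 6 of the 6 control sets at every level except D4, where it had more in 5. Without DMSO replicate A it had more in 6, 6, 4, 4, 4, 4 and 5 sets from D1 to D7, without B in 6, 6, 5, 4, 5, 5 and 6, and without C in 6 at every level except D4 (5). At D1 the second chemicals had between 244 and 1728 genes called and the first between 40 and 169, and at D7 between 28 and 429 against between 0 and 2 (at D7, exact two-sided sign-flip test over the 6 sets, p = 0.03125, the smallest p that 6 sets can give, a comparison chosen after the counts were seen). Without DMSO replicate A the D7 counts of the second chemicals were 69, 2, 126, 1, 40 and 18 in the order of the control sets, against 0, 0, 0, 1, 0 and 0 in the first, so the counts were equal in the set of cetirizine and fipronil carboxamide and the exact sign-flip p was 0.0625. Without DMSO replicate B they were 94, 1, 259, 22, 133 and 31 against 0, 0, 0, 2, 0 and 3. Without DMSO replicate C they were 319, 42, 483, 38, 427 and 141 against 1, 0, 0, 2, 0 and 0, and the exact sign-flip p was 0.03125 without B and without C. This difference stands beside every count given below, at each level, for a chemical listed second, which are gabapentin, 2-tert-butyl-4-methoxyphenol, 4-chlorophenyl methyl sulfone, fipronil carboxamide, cis-nonachlordane and 3,4-dichlorophenyl isocyanate.

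**Figure D1:**
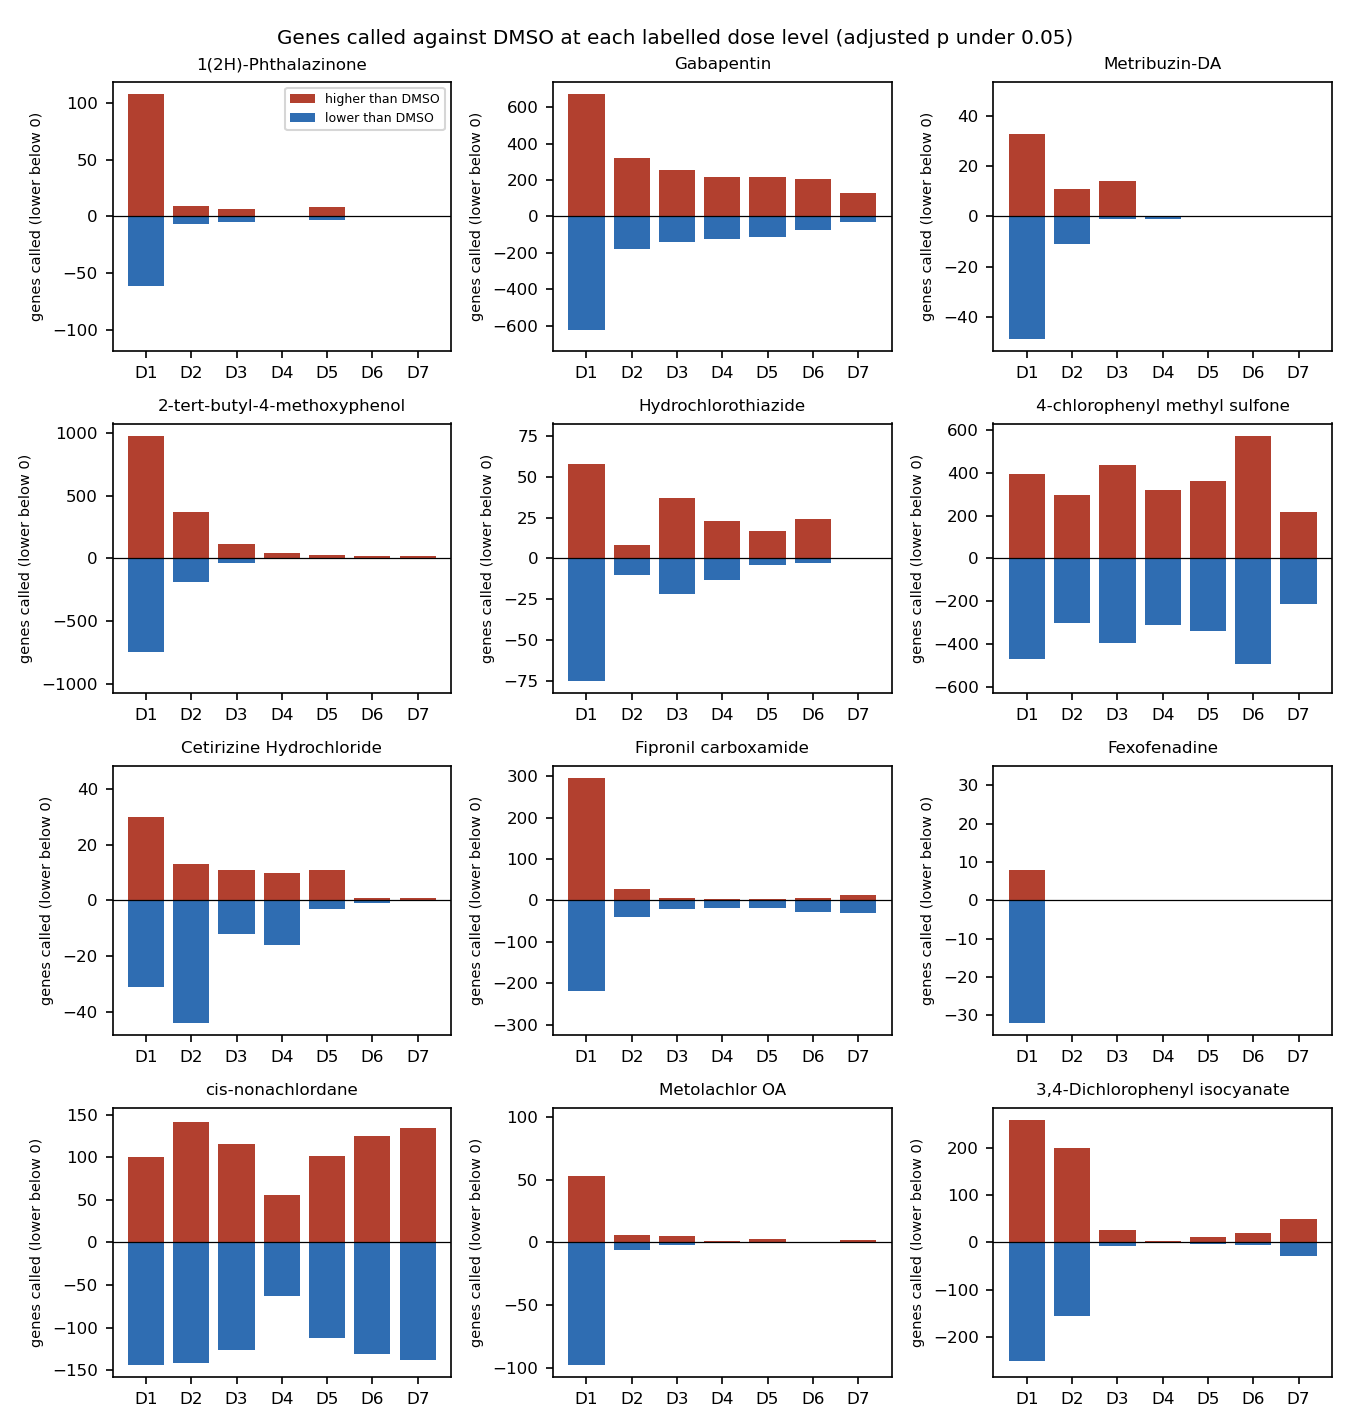
Number of genes called against DMSO (vertical axis, genes higher than DMSO above 0 and genes lower than DMSO below 0, each panel on its own scale) at each labelled dose level (horizontal axis) for the 12 chemicals, by edgeR's quasi-likelihood test at an adjusted p under 0.05 with 3 libraries per group. Higher and lower genes summed are most at D1 in 10 panels, while 4-chlorophenyl methyl sulfone keeps between 429 and 1067 genes and cis-nonachlordane between 119 and 282 at all 7 levels.

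In 1(2H)-phthalazinone, a bicyclic aromatic lactam, Rsub_05036 rose at D1 from 53.6 ± 3.67 to 125 ± 13.4 CPM (counts scaled to the library total, mean ± SD, n = 3), a log2 fold change of 1.22 ± 0.177 (SE). Rsub_10133 rose from 592 ± 74.7 to 1336 ± 225 CPM. Among the falls, Rsub_04324 changed by a log2 fold change of −1.41 ± 0.291 and Rsub_02610 by −1.34 ± 0.206. At D1 108 genes were higher and 61 lower than DMSO, and 116 of 9255 genes tested differed among DMSO and the 7 levels. At D4, D6 and D7 edgeR's quasi-likelihood test called 0 genes, with 805, 651 and 486 genes at an unadjusted p under 0.05, and DESeq2 called 24, 0 and 0. With the replicate letter as a block edgeR called 41, 28 and 21 genes at these levels. With no low-count filter edgeR called 20, 14 and 21 genes there, and with a single DMSO or D1 library left out at most 5, 1 and 1. Single libraries of D4, D6 and D7 were not left out. RLE scaling and a minimum mean of 10 counts each gave 2 at D4. The D1 count was 83 without DMSO replicate B, 87 without D1 replicate B and 91 without D1 replicate C, and the count over all levels was 71 without D1 replicate B. Rsub_04324 missed the threshold without DMSO replicate B (log2 fold change −1.24) and without D1 replicate C (−1.15).

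Gabapentin, an anticonvulsant drug, differed from DMSO in 1297 genes at D1, 673 higher and 624 lower. Rsub_06872 rose from 37.5 ± 11.1 to 335 ± 317 CPM, a log2 fold change of 3.18 ± 0.363, with an SD among the 3 treated libraries nearly as large as their mean. Rsub_09701 rose from 10.4 ± 4.72 to 68.4 ± 31.5 CPM. Rsub_12662 fell from 28.8 ± 7.67 to 3.31 ± 1.6 CPM, and Rsub_12294 from 21.8 ± 3.06 to 3.09 ± 2.52 CPM. Both genes that rose differed from DMSO by the test at D1 alone, whereas Rsub_12662 was also lower at D2 (log2 fold change −1.76), D3, D5 and D6. From D2 to D7 the number of genes called was 494, 393, 336, 332, 280 and 161, and 115 genes were called at 6 or more levels in one direction, 93 of them higher. Without DMSO replicate A the counts at D6 and D7 were 175 and 69, without B those from D2 to D7 were 296, 226, 193, 198, 180 and 94, and without C that at D7 was 319. The genes called at 6 or more levels numbered 68 without DMSO replicate A and 66 without B. Over all levels 1081 of 9284 genes differed. Without D1 replicate C the D1 count was 808 and the log2 fold change of Rsub_06872 was 2.09, and without D1 replicate B that of Rsub_12294 was −3.64.

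The direct test between the chemicals of this control set found 484 genes that differed between phthalazinone and gabapentin at D1 and between 6 and 46 at each of the other levels. That test compares treated libraries, but the DMSO libraries enter its filter, scaling and estimate of the spread.

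In metribuzin-DA, a deaminated transformation product of the herbicide metribuzin, Rsub_00048 rose at D1 from 31.2 ± 9.09 to 111 ± 24.4 CPM, a log2 fold change of 1.81 ± 0.273. This gene was also higher at D2 (1.71) and D3 (1.55). Rsub_08453 rose by 1.18 ± 0.232 at D1, by 1.49 at D2 and by 1.61 at D3 on the log2 scale. Rsub_12462 fell from 51.0 ± 7.37 to 16.7 ± 3.85 CPM and Rsub_01112 from 84.1 ± 13.5 to 30.1 ± 7.52 CPM. At D1 82 genes differed from DMSO, 33 higher and 49 lower, followed by 22, 15 and 1 at D2, D3 and D4, and 80 of 9210 genes differed over all levels. edgeR called 0 genes at D5, D6 and D7, where 515, 427 and 314 genes had an unadjusted p under 0.05 and DESeq2 called 0, 1 and 1. With the replicate letter as a block edgeR called 3, 3 and 4. With no low-count filter edgeR called 8, 6 and 5, and with the filter and a single DMSO or D1 library left out at most 2 at D7. Without DMSO replicate A the D2 and D3 counts were 6 and 9, without B those at D2, D3 and D4 were 5, 3 and 0, and without C those at D3 and D4 were 5 and 2. At D1 the count was 24 without DMSO replicate A, 17 without DMSO replicate B, and 42, 10 and 128 without D1 replicates A, B and C, and the count over all levels was 41 without D1 replicate B. Without D1 replicate B the calls of Rsub_08453 (log2 fold change 0.85) and Rsub_01112 (−1.45) ended, and that of Rsub_01112 also ended without DMSO replicate B (−1.33).

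2-tert-butyl-4-methoxyphenol, a phenolic antioxidant and a component of the food additive butylated hydroxyanisole, gave the largest fold changes among the named genes. Rsub_07717 stood at 0.632 ± 0.563 CPM in DMSO, where the 3 libraries held 2 counts in all, and at 160 ± 32.0 CPM at D1, where they held 548 counts. The ratio of these counts per library total was 263, with an exact Poisson 95% interval of 72.5 to 2180 that covers counting error only. Rsub_11816 rose from 3.54 ± 0.692 to 317 ± 109 CPM, a log2 fold change of 6.48 ± 0.362, and was also higher at D2 (5.71) and D3 (3.35). Rsub_12322 fell from 28.9 ± 4.04 CPM, or 99 counts, to 0.272 ± 0.471 CPM, or 1 count, a 103-fold lower rate with a 95% counting interval of 18.1 to 4110. Rsub_11220 fell from 81.5 ± 3.33 to 1.38 ± 1.27 CPM and was also lower at D2 (log2 fold change −2.49) and D3 (−1.36). At D1 981 genes were higher and 747 lower, 477 and 273 of them by more than 2-fold, and from D2 to D7 the counts were 556, 152, 55, 26, 24 and 28. Over all levels 951 of 9435 genes differed. Leaving out any single DMSO or D1 library moved neither this count nor the D1 count by over 1.5 times. D1 replicate A lay apart from B and C, with chi-square values per degree of freedom of 8.58 and 9.70, against 2.32 between B and C. Without it 2114 genes were called at D1. From D2 to D7 the counts were 341, 66, 23, 1, 4 and 2 without DMSO replicate A and 362, 85, 24, 3, 6 and 1 without B, and the D6 count was 39 without C. The fitted log2 fold changes of Rsub_07717 and Rsub_12322, 7.87 and −6.16, depend on the prior count and were 7.26 without DMSO replicate C and −8.08 without D1 replicate B, and that of Rsub_11220 was −6.32 without D1 replicate C.

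Between metribuzin-DA and 2-tert-butyl-4-methoxyphenol, the direct test found 1527 genes that differed at D1, 658 at D2 and between 63 and 196 at each of the other levels.

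**Figure D2:**
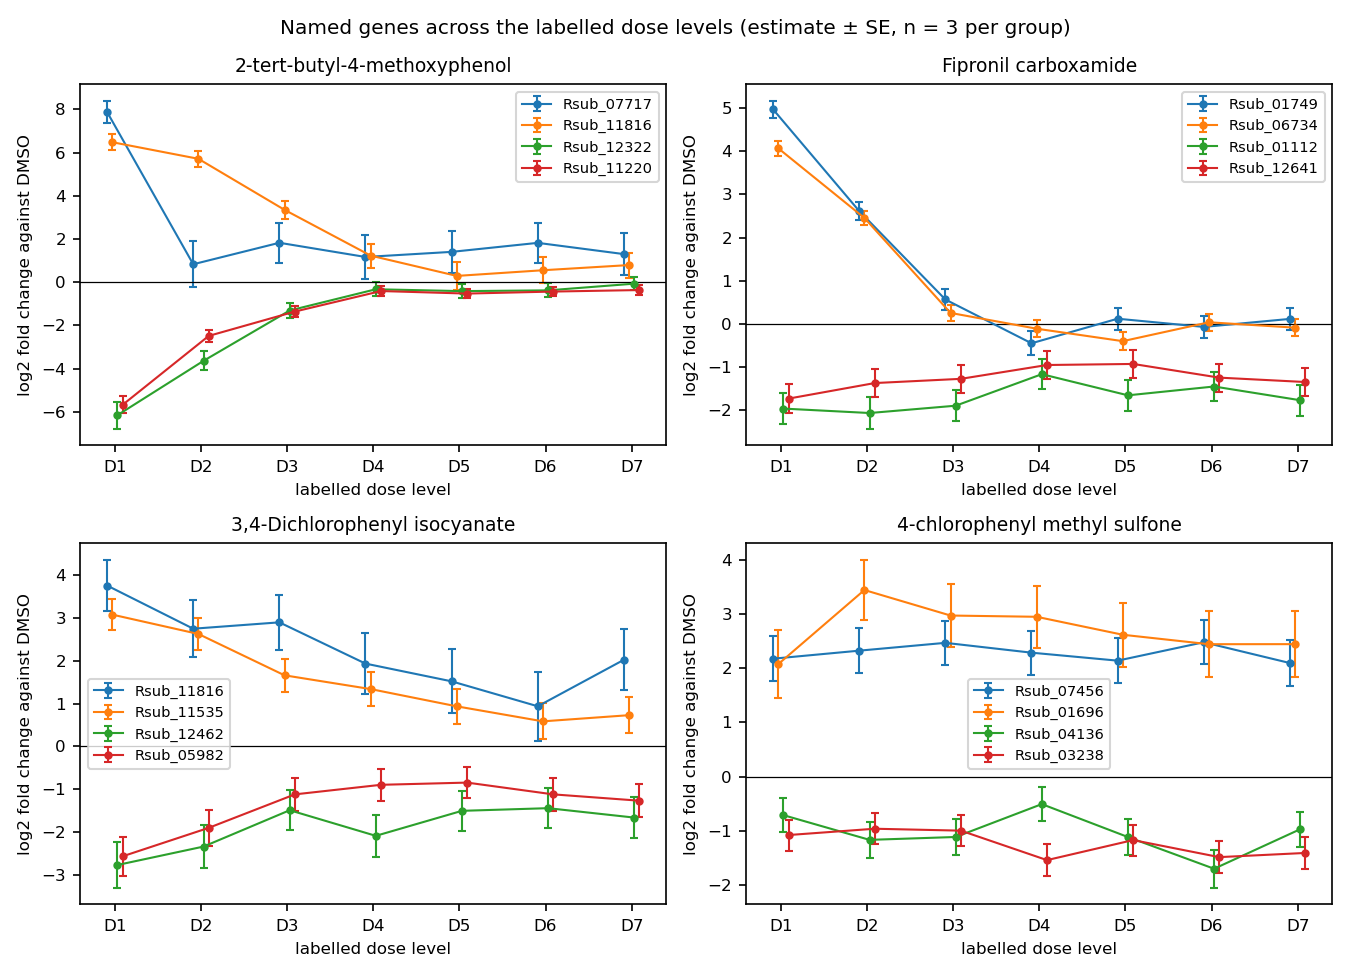
Log2 fold change against DMSO (vertical axis) at each labelled dose level (horizontal axis) for the 4 named genes of 4 chemicals; points are edgeR estimates and bars their standard errors, with 3 libraries per group, and lines join the levels of one gene. The estimates of Rsub_07717 and of Rsub_12322 at D1 in the first panel rest on 2 and 1 counts in one of the groups and depend on the prior count, and Rsub_07456 and Rsub_01696 stay above 2 at all 7 levels of 4-chlorophenyl methyl sulfone.

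In hydrochlorothiazide, a thiazide diuretic, Rsub_09261 fell at D1 from 46.1 ± 3.4 to 9.48 ± 2.29 CPM, a log2 fold change of −2.27 ± 0.394, and Rsub_12849 fell from 178 ± 42.2 to 55.3 ± 15.9 CPM, a log2 fold change of −1.70 ± 0.183. Rsub_05674 rose by 1.27 ± 0.256 on the log2 scale. Rsub_09319 rose by 1.20 ± 0.316, and at D2 and D3 by 1.51 and 1.85. At D1 58 genes were higher and 75 lower, D2 to D6 had between 18 and 59 genes called, and 82 of 9052 genes differed over all levels. At D7 edgeR called 0 genes, with 480 at an unadjusted p under 0.05, and DESeq2 called 0. With no low-count filter edgeR called 14, and with the replicate letter as a block 25. From D2 to D6 the counts were 1, 10, 0, 0 and 1 without DMSO replicate A and 9, 31, 3, 6 and 8 without B, and the D5 count was 33 without C. The D1 count was 47 without DMSO replicate A, 73 without DMSO replicate B, 63 without D1 replicate B and 59 without D1 replicate C, and the count over all levels was 42 and 47 without DMSO replicates A and B and 53, 24 and 42 without D1 replicates A, B and C. Rsub_05674 missed the threshold without DMSO replicate A (log2 fold change 1.01), and Rsub_09319 without DMSO replicate A (0.96), DMSO replicate C (1.18), D1 replicate B (1.13) or D1 replicate C (0.98).

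4-chlorophenyl methyl sulfone, a chlorinated aryl sulfone, differed from DMSO in between 429 and 1067 genes at every level, the most at D6 with 574 higher and 493 lower. Rsub_07456 rose at D6 from 6.12 ± 1.61 to 34.9 ± 2.43 CPM, a log2 fold change of 2.48 ± 0.403, and its log2 fold change lay between 2.09 and 2.48 over the 7 levels, each past the threshold. Rsub_01696 rose from 2.19 ± 1.89 to 11.9 ± 2.4 CPM and was likewise higher at all 7 levels. Rsub_04136 fell from 37.6 ± 10.1 to 11.5 ± 1.52 CPM, and Rsub_03238 from 65.8 ± 11.7 to 23.3 ± 6.59 CPM with a lower value past the threshold at each level. In all 325 genes, 161 higher and 164 lower, were called at 6 or more levels in one direction. Over DMSO and the 7 levels 659 of 9176 genes differed, against 20 among D1 to D7 with the DMSO libraries left out, an alternative added after the data were seen. The level counts lay between 126 and 560 without DMSO replicate A and between 259 and 777 without B. Genes called at 6 or more levels then numbered 108 and 201. The count over all levels was 292 without DMSO replicate A and 375 without DMSO replicate B, and the D6 count was 560 without DMSO replicate A and 550 without D6 replicate C. Without DMSO replicate C the log2 fold change of Rsub_01696 was 1.81.

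In the direct test between hydrochlorothiazide and 4-chlorophenyl methyl sulfone, between 6 and 130 genes differed at a level, the most at D6.

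In cetirizine hydrochloride, an antihistamine, Rsub_03879 fell at D1 from 150 ± 101 to 14.6 ± 2.84 CPM, a log2 fold change of −3.36 ± 0.549 (−2.09 at D2). Rsub_01112 changed by a log2 fold change of −1.13 ± 0.278 at D1 and −1.35 at D2. Rsub_12322 rose from 9.17 ± 1.05 to 38.7 ± 8.0 CPM, a log2 fold change of 2.06 ± 0.436, and Rsub_00475 from 46.0 ± 11.0 to 117 ± 18.3 CPM. At D1 30 genes were higher and 31 lower, from D2 to D7 the number called was 57, 23, 26, 14, 2 and 1, and 93 of 9160 genes differed over all levels. From D2 to D7 the counts were 19, 4, 20, 4, 9 and 1 without DMSO replicate A, 61, 34, 45, 32, 16 and 2 without B, and 40, 8, 16, 9, 0 and 2 without C. At D1 the count was 34 without DMSO replicate A, 37 without D1 replicate A and 21 without D1 replicate B, and the count over all levels was 60 without D1 replicate B. Without DMSO replicate A the log2 fold change of Rsub_03879 was −2.71. Rsub_12322 missed the threshold without DMSO replicate A (1.97) or D1 replicate B (1.88), and Rsub_01112 without DMSO replicate A (−0.89), DMSO replicate B (−1.16), D1 replicate B (−0.91) or D1 replicate C (−1.02).

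In fipronil carboxamide, a transformation product of the insecticide fipronil, Rsub_01749 rose at D1 from 27.0 ± 1.96 to 853 ± 41.0 CPM, a log2 fold change of 4.98 ± 0.197. Rsub_06734 rose from 55.6 ± 2.27 to 937 ± 85.9 CPM, a log2 fold change of 4.07 ± 0.171. At D2 the log2 fold changes of these genes were 2.62 and 2.45, and from D3 to D7 neither passed the threshold. Rsub_01112 fell at D1 from 87.8 ± 25.8 to 22.1 ± 3.78 CPM and was lower at every level except D4, where edgeR's quasi-likelihood test gave an adjusted p of 0.15 (log2 fold change −1.17), while Rsub_12641 changed by a log2 fold change of −1.74 ± 0.337 at D1. At D1 296 genes were higher and 219 lower, against 67 genes at D2 and between 21 and 43 at D3 to D7, and 214 of 9144 genes differed over all levels. Without DMSO replicate A 21 genes were called at D2 and between 1 and 4 at D3 to D7, while without B there were 48, 43 and 22 at D3, D5 and D7. The D1 count was 159 without DMSO replicate A, 232 without D1 replicate B and 338 without D1 replicate C, and the count over all levels was 140 without DMSO replicate A and 80 without D1 replicate B.

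Cetirizine and fipronil carboxamide differed directly in 570 genes at D1, 17 at D2, 2 at D4 and 17 at D7. At D3, D5 and D6 edgeR's quasi-likelihood test called 0, with 735, 698 and 733 genes at an unadjusted p under 0.05.

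In fexofenadine, an antihistamine, Rsub_09261 fell at D1 from 106 ± 36.5 to 36.5 ± 11.9 CPM, a log2 fold change of −1.51 ± 0.308, and Rsub_12711 fell from 45.9 ± 12.5 to 16.4 ± 3.92 CPM. Rsub_11267 rose from 27.7 ± 7.37 to 55.7 ± 4.51 CPM and Rsub_04768 from 112 ± 24.1 to 201 ± 41.8 CPM. At D1 8 genes were higher and 32 lower, and 58 of 9564 genes differed over all levels. edgeR with its low-count filter and DESeq2 each called 0 genes at every level from D2 to D7, where edgeR gave 534, 530, 760, 656, 614 and 473 genes at an unadjusted p under 0.05. With the replicate letter as a block edgeR called 9, 21, 113, 35, 29 and 7 genes at these levels. With no low-count filter and no block it called 4, 5, 24, 10, 8 and 5. With a single DMSO or D1 library left out it called at most 2 at any of them, and single libraries of D2 to D7 were not left out. The D1 count was 1 without DMSO replicate B, 8 without D1 replicate B and 13 without D1 replicate C, and the count over all levels was 37, 19 and 30 without D1 replicates A, B and C. Each of the 4 named genes missed the threshold without DMSO replicate B (log2 fold changes −1.38, −1.23, 0.84 and 0.68 in the order above) and without D1 replicate B (−1.53, −1.36, 1.01 and 0.69), Rsub_09261 also without DMSO replicate C (−1.33) or D1 replicate A (−1.28), and Rsub_11267 also without DMSO replicate C (0.90), D1 replicate A (0.90) or D1 replicate C (1.01).

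cis-nonachlordane, an organochlorine compound related to the insecticide chlordane, differed from DMSO in between 119 and 282 genes at each level. At D2, with 141 genes higher and 141 lower, Rsub_02681 rose from 16.9 ± 6.36 to 46.1 ± 12.1 CPM and Rsub_02655 from 62.1 ± 28.9 to 150 ± 41.7 CPM, and both were higher at every level except D1. Rsub_02610 fell from 391 ± 123 to 165 ± 22.0 CPM, with a log2 fold change between −1.45 and −1.10 over the 7 levels, each past the threshold. Rsub_05990 changed by a log2 fold change of −1.51 ± 0.302 at D2. In all 65 genes were called at 6 or more levels in one direction, against 3, 20 and 162 without DMSO replicates A, B and C. Without a single treated library they numbered between 34 and 100, and 9 of these 21 libraries moved the count by over 1.5 times. The level counts lay between 7 and 137 without DMSO replicate A, between 24 and 133 without B and between 287 and 427 without C. Over all levels 85 of 9488 genes differed, against 2 among D1 to D7 with DMSO left out, where a slope over D1 to D7 by edgeR gave 0, with 615 genes at an unadjusted p under 0.05. The D2 count was 18 without DMSO replicate A, 91 without DMSO replicate B, 40 without D2 replicate B and 54 without D2 replicate C, and the count over all levels was 4 and 11 without DMSO replicates A and B. Without DMSO replicate A Rsub_02681 (log2 fold change 1.17), Rsub_02655 (1.04) and Rsub_05990 (−1.27) missed the threshold, as did Rsub_02655 without DMSO replicate B (1.13), Rsub_02655 (1.25) and Rsub_05990 (−1.37) without D2 replicate B, and Rsub_02681 (1.25) and Rsub_02655 (1.07) without D2 replicate C.

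Directly compared, fexofenadine and cis-nonachlordane differed in 8 genes at D1, 79 at D2, 142 at D3, 143 at D4, 183 at D5, 310 at D6 and 411 at D7.

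Metolachlor OA, the oxanilic acid degradate of the herbicide metolachlor, showed a rise of Rsub_11267 at D1 from 40.7 ± 7.04 to 111 ± 9.29 CPM, a log2 fold change of 1.46 ± 0.197, and of Rsub_02329 from 39.2 ± 14.0 to 101 ± 9.88 CPM. Rsub_09261 fell from 115 ± 36.2 to 29.0 ± 1.9 CPM, a log2 fold change of −1.97 ± 0.415, and Rsub_01016 from 29.1 ± 4.69 to 7.9 ± 1.23 CPM. At D1 53 genes were higher and 98 lower, from D2 to D7 the number called was 12, 7, 1, 3, 0 and 2, and 234 of 9436 genes differed over all levels. At D6, where edgeR called 0, 680 genes had an unadjusted p under 0.05 and DESeq2 called 8. With no low-count filter edgeR called 28, and with the filter and a single DMSO or D1 library left out at most 2. With the replicate letter as a block it called 27. From D2 to D7 the counts were 3, 3, 1, 0, 0 and 0 without DMSO replicate A, 7, 12, 2, 2, 2 and 3 without B, and 7, 6, 1, 1, 1 and 0 without C. Without single libraries the D1 count was 39 and 91 without DMSO replicates A and B and 64 and 43 without D1 replicates B and C, and the count over all levels was 117 and 109 without D1 replicates B and C. Rsub_02329 missed the threshold without DMSO replicate A (log2 fold change 1.18), Rsub_09261 without D1 replicate C (−1.91), and Rsub_01016 without DMSO replicate A (−1.73) or D1 replicates A, B or C (−1.78, −1.85 and −1.99).

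In 3,4-dichlorophenyl isocyanate, a reactive chlorinated aromatic isocyanate, Rsub_11816 rose at D1 from 1.81 ± 1.12 to 26.2 ± 5.05 CPM, a log2 fold change of 3.76 ± 0.6, and Rsub_11535 rose from 25.8 ± 7.22 to 220 ± 58.3 CPM, a log2 fold change of 3.08 ± 0.361. Both were also higher at D2 (2.75 and 2.63) and D3 (2.90 and 1.66). Rsub_12462 fell from 74.4 ± 19.2 to 10.8 ± 6.86 CPM, and Rsub_05982 from 23.2 ± 11.4 to 3.77 ± 0.637 CPM. At D1 260 genes were higher and 252 lower, from D2 to D7 the number called was 357, 34, 5, 16, 26 and 77, and 234 of 9341 genes differed over all levels. From D2 to D7 the counts were 160, 0, 0, 0, 0 and 18 without DMSO replicate A, 156, 0, 0, 0, 2 and 31 without B, and 406, 39, 23, 26, 52 and 141 without C. The D1 count was 220 and 287 without DMSO replicates A and B and 204 and 312 without D1 replicates B and C, and the count over all levels was 136, 153 and 139 without DMSO replicate A, DMSO replicate B and D1 replicate B. Without DMSO replicate A the log2 fold change of Rsub_11816 was 4.40, and without D1 replicate A that of Rsub_12462 was −3.36.

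Metolachlor OA and 3,4-dichlorophenyl isocyanate differed directly in 263 genes at D1, 138 at D2, between 39 and 63 at D3 to D5, 122 at D6 and 199 at D7.

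The calls of different chemicals were then compared. Rsub_11816 passed the low-count filter in 2 chemicals only, 2-tert-butyl-4-methoxyphenol and 3,4-dichlorophenyl isocyanate, with 12 and 5 counts in their DMSO libraries. A gene this low in DMSO passes the filter through groups where it is high, so its rise in both is no sign of agreement. In the other chemicals it was not tested. Rsub_12322 was lower in 2-tert-butyl-4-methoxyphenol and higher in cetirizine. Some named rises were larger at D1 in another chemical, where the gene was not named. Rsub_01749 was called higher at D1 in 2 chemicals and lower in 1, with log2 fold changes up to 5.82. Rsub_06734 was called higher in 2 (up to 4.63) and Rsub_11535 in 3 (up to 3.63), and neither was called lower. Rsub_04768 was higher than DMSO at D1 in all 12 chemicals, with log2 fold changes from 0.48 to 1.68, and Rsub_01112 was lower in 10, with log2 fold changes from −3.09 to −1.06 over all 12. Rsub_09770, singled out after its values were seen, was also higher in all 12, and Rsub_00223, singled out in the same way, was lower in 10. Among the 8715 genes tested in every chemical, 498 were called at D1 in one direction in 3 or more of the 6 control sets, 225 higher and 273 lower. A set counted when either of its 2 chemicals called the gene and neither called the opposite direction. The chemicals listed second had between 244 and 1728 genes called at D1, those listed first between 40 and 169. Independent lists of the same sizes gave at most 51 in 1000 draws, and lists matched on mean expression at most 112. Such draws treat genes as independent, so genes that vary together could exceed them. In 28 genes the direction was shared by all 6 control sets. Without a single DMSO library the number recurrent lay between 414 and 514. Without DMSO replicate A, B or C in every set it was 195, 289 and 523, with 3, 8 and 28 genes shared by all 6 sets.

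At the fullest level, 11 chemicals had 50 or more calls, which made 55 pairs. In each of the 50 pairs with different DMSO libraries, more genes changed in the same direction than independent lists would share, n1 × n2 / N summed over both directions. For 2-tert-butyl-4-methoxyphenol and 3,4-dichlorophenyl isocyanate, for instance, 174 genes were higher in both and 116 lower in both, or 290 in the same direction against 46.7 for independent lists, and 10 went in opposite directions against 46.5. In 8 of the 50 pairs the opposite calls also outnumbered those of independent lists, as for 2-tert-butyl-4-methoxyphenol and cetirizine with 13 against 5.55. The 5 pairs that shared DMSO libraries had between 26 and 137 genes changed in the same direction, against between 1.72 and 11.9 for independent lists. Simulated unchanged groups against the same controls shared at most 1 call. With no changed gene drawn, few calls can arise at all, so this cannot show how many shared calls come from the shared controls. For phthalazinone and gabapentin the covariance of log2 fold changes across genes, which are not independent replicates, was 0.0976 against 0.042 in the simulation, with correlations of 0.533 and 0.499. The differences in covariance were 0.0395, 0.0414, 0.0139 and 0.0445 in the other 4 pairs, in the order of the control sets, with correlations of 0.367, 0.525, 0.386 and 0.595 against simulated 0.49, 0.506, 0.495 and 0.539. With 3 DMSO libraries the controls could not be split into parts with a pair of libraries or more each, so part of the excess in these pairs may come from the shared controls.

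Genes recurrent at D1 in 3 or more of the other control sets were followed in each chemical in turn, with between 289 and 454 genes per chemical. Their median log2 fold change, signed by the direction in the other sets, was above 0 at D1 in all 12 chemicals and lay between 0.19 and 0.36 in those listed first and between 0.38 and 0.71 in those listed second. The lists drew on more D1 calls of chemicals listed second (244 to 1728 genes each) than of those listed first (40 to 169). Lists for different sets also share source chemicals. A higher median in the second chemical may follow in part from this, so the 6 sets are no independent support for it. The median was higher in the second chemical in 6 of 6 sets at each of the 7 levels, also without DMSO replicate A, B or C. At D7 it lay between −0.03 and 0.05 in the chemicals listed first and between 0.22 and 0.40 in those listed second (at D7, exact two-sided sign-flip test over 6 sets, p = 0.03125, the smallest p possible, chosen after the values were seen). Without DMSO replicate A these D7 ranges were −0.13 to −0.0245 and 0.114 to 0.346.

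**Figure D3:**
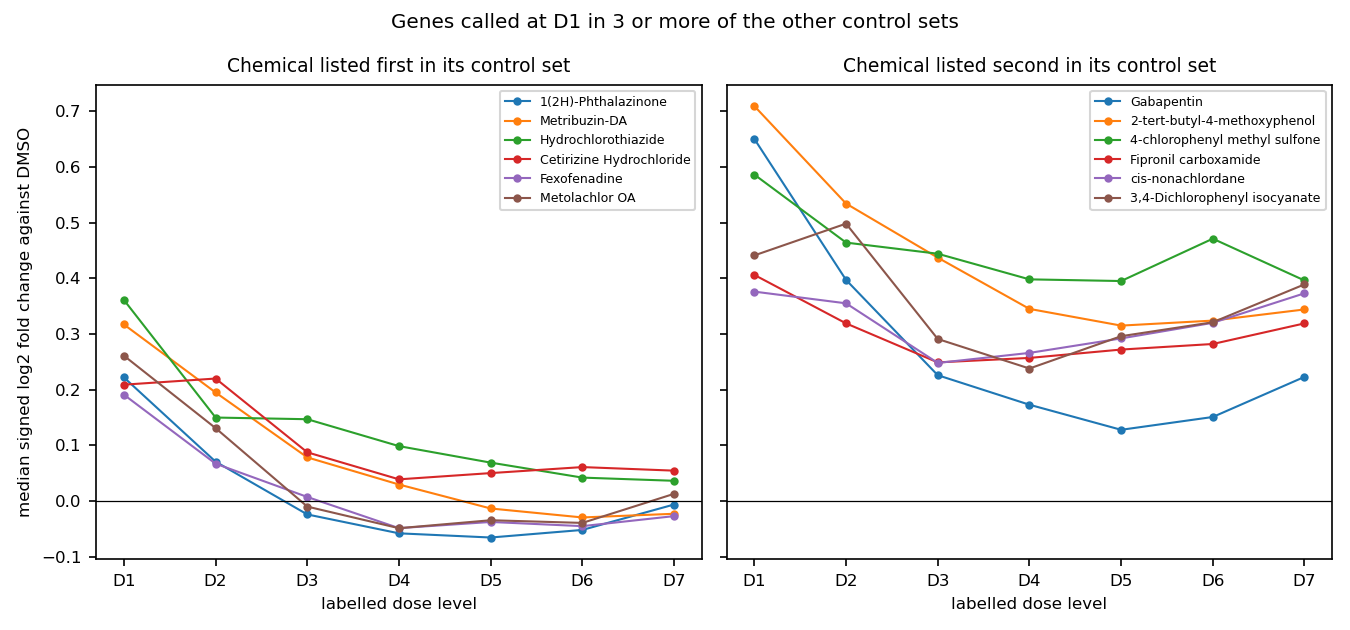
Median log2 fold change against DMSO (vertical axis), signed by the direction in the other control sets, at each labelled dose level (horizontal axis) for genes called at D1 in 3 or more of the 5 control sets other than the chemical's own; each line is a chemical, on the left those listed first in their control set and on the right those listed second. At D1 the lines lie between 0.19 and 0.36 on the left and between 0.38 and 0.71 on the right, and at D7 between −0.03 and 0.05 on the left and between 0.22 and 0.40 on the right.

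The DMSO libraries of the 6 control sets were compared with one another as a measure of the background between sets. Of 9242 genes tested, 3259 (35.3%) differed among the sets by edgeR's quasi-likelihood test, more than in any comparison of a chemical with its own DMSO libraries. The labels give no date or plate for a set, so a difference between sets cannot be told apart from one between such batches, and fold changes were computed only within a set.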

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

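The tests with the DMSO libraries left out and those without single treated libraries, and the exclusions for genes called at 6 or more levels, were chosen only after the results were seen. The tests of the gene lists under other correlations and by fry were not run because the identifiers came without names. Of the 48 named gene results, 26 lost their call under at least 1 setting and none changed direction. DESeq2 gave no adjusted p for 13 of the 48, and these are not counted as lost. Library totals with a median of 1083755 counts and 3 libraries per group limited the calls, since many changes of 1.5-fold were missed in simulated counts. Leaving out a replicate in every group removes 8 of the 24 libraries, so fewer calls follow in part from fewer samples. For the other shifts below the cause was not tested.

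Neither RLE scaling nor a minimum mean of 10 counts moved any of the 12 counts over all levels by more than 1.5 times. DESeq2 gave 203 genes for 1(2H)-phthalazinone, 180 for metribuzin-DA, 214 for hydrochlorothiazide, 157 for cetirizine, 339 for fipronil carboxamide, 107 for fexofenadine, 258 for cis-nonachlordane and 405 for 3,4-dichlorophenyl isocyanate. With no low-count filter the counts were 318 for 1(2H)-phthalazinone, 275 for metribuzin-DA, 316 for hydrochlorothiazide, 220 for cetirizine, 513 for fipronil carboxamide, 209 for fexofenadine, 350 for cis-nonachlordane, 504 for metolachlor OA and 472 for 3,4-dichlorophenyl isocyanate. A slope over D1 to D7, a test of another question without DMSO, gave 351 for 1(2H)-phthalazinone, 407 for metribuzin-DA, 23 for 4-chlorophenyl methyl sulfone, 51 for cetirizine, 72 for fipronil carboxamide, 170 for fexofenadine, 520 for metolachlor OA and, by edgeR's quasi-likelihood test, 0 for cis-nonachlordane, with 615 genes at an unadjusted p under 0.05. With DMSO left out the test gave 37 for hydrochlorothiazide, 20 for 4-chlorophenyl methyl sulfone, 118 for fipronil carboxamide, 2 for cis-nonachlordane and 116 for 3,4-dichlorophenyl isocyanate. One fit for both chemicals of a control set gave 36 for metribuzin-DA, 135 for hydrochlorothiazide, 14 for fexofenadine, 167 for cis-nonachlordane, 72 for metolachlor OA and 443 for 3,4-dichlorophenyl isocyanate. Adjustment over all 12 chemicals gave 141 for metribuzin-DA, 159 for hydrochlorothiazide, 148 for cetirizine, 113 for fexofenadine and 159 for cis-nonachlordane.

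Leaving out a replicate in every group or a single library gave from 5 to 350 genes for 1(2H)-phthalazinone, 139 to 1200 for gabapentin, 3 to 107 for metribuzin-DA, 297 to 1203 for 2-tert-butyl-4-methoxyphenol, 3 to 197 for hydrochlorothiazide, 56 to 612 for 4-chlorophenyl methyl sulfone, 19 to 100 for cetirizine, 16 to 237 for fipronil carboxamide, 8 to 79 for fexofenadine, 1 to 250 for cis-nonachlordane, 32 to 295 for metolachlor OA and 22 to 237 for 3,4-dichlorophenyl isocyanate. Of the 84 counts of single levels, leaving out DMSO replicate A moved 61 by over 1.5 times (55 of them lower), B 58 (47 lower) and C 31 (10 lower). Of the 60 counts from D2 to D6 these moved 46, 44 and 25. Of 70 level counts in the chemicals with the most at D1, leaving out D1 replicate A, B or C moved 9, 15 and 15. Single treated libraries of the other levels were left out only for the genes called at 6 or more levels. These then numbered 80 to 114 in gabapentin, 249 to 338 in 4-chlorophenyl methyl sulfone and 34 to 100 in cis-nonachlordane, against 115, 325 and 65. Among the DMSO sets 1324 to 2741 genes differed with a replicate left out, against 3259 with all libraries, and 3266 with RLE scaling.

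With the replicate letter as a replicate block the counts were 340 for 1(2H)-phthalazinone, 222 for metribuzin-DA, 1474 for 2-tert-butyl-4-methoxyphenol, 486 for hydrochlorothiazide, 1187 for 4-chlorophenyl methyl sulfone, 219 for cetirizine, 444 for fipronil carboxamide, 439 for fexofenadine, 684 for cis-nonachlordane, 624 for metolachlor OA and 984 for 3,4-dichlorophenyl isocyanate, all higher than without the block. The count of 1467 for gabapentin was within 1.5 times of its 1081. The DMSO sets gave 3808. No named gene lost its call under the block. At the 14 levels where 0 genes were called without it, the block gave between 3 and 113 (9, 21, 113, 35, 29 and 7 at D2 to D7 of fexofenadine), and edgeR with no low-count filter between 4 and 28. Fexofenadine, with the fewest genes over all levels without the block, had more than cetirizine, metribuzin-DA and 1(2H)-phthalazinone with it. The labels do not say what a letter marks. After group means were removed, libraries with the same letter correlated at a mean of 0.0238 to 0.127 over the 12 chemicals, with negative correlations in each. The letters were therefore not taken to pair samples, although single negative correlations do not exclude a pairing. Between 17 and 24 of the 24 libraries of a chemical were closest to their own letter, a hint from the data and not from the design. The counts without the block may thus leave out a structure by letter.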

Other observations

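The comparison of library totals with the level of genes called at 6 or more levels, the counts without single libraries, that of D1 with D7 shifts in recurrent genes and the test of the order of chemicals in the labels were chosen only after the results were seen.

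In gabapentin, 4-chlorophenyl methyl sulfone and cis-nonachlordane, 115, 325 and 65 genes were called at 6 or more of the 7 levels in one direction (68, 108 and 3 without DMSO replicate A). Unequal library depth is argued against: within groups the slope of their scaled level on the log2 library total gave a log2 shift of at most 0.0419, 0.0644 and 0.012 at any level (0.097, 0.136 and 0.0623 with 2 SE added), beside a median absolute shift of 0.75, 0.694 and 0.766, while thinning the libraries, the test set beforehand, and comparing raw totals could not decide because fold changes are scaled by library total. DMSO libraries that lie apart would shift the partner chemical of the same control set equally, and the partner's median shift, taken at each of its 7 levels, was 0.462 to 0.667, 0.344 to 0.588 and 0.155 to 0.508 times as large (middle values 0.589, 0.545 and 0.206), which leaves this open because noise in the shared DMSO libraries alone would also give ratios above 0 in genes called against them. A batch in which the treated libraries were prepared apart from their DMSO libraries may also account for such genes, and 14, 33 and 40 of them differed directly from the partner at D7. Shared controls, such a batch and an effect of the chemical at every level cannot be told apart here, because the labels give no plate or date.

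At D1, 498 genes were called in one direction in 3 or more of the 6 control sets, which share no libraries, against at most 51 in 1000 draws of independent lists, and a response common to several chemicals is a hypothesis that goes with this. Draws matched on mean expression reached at most 112, which argues against abundance alone. If a difference of the DMSO libraries from all treated libraries alike were the only cause, these genes would shift as much at D7 as at D1. The ratio was −0.141 to 0.262 in the chemicals listed first and 0.344 to 0.991 in those listed second (median 0.303 over the 12). This argues against it as the only cause in those listed first. The genes were chosen by D1 calls, so a D1 effect on top of such a difference would also lower the ratio, and a part of it stays open. The ratio ran from −0.141 in fexofenadine to 0.991 in cis-nonachlordane, which share their DMSO libraries. At D7 the median shift lay between −0.0269 and 0.0547 in the chemicals listed first and between 0.223 and 0.396 in those listed second against the same DMSO libraries. Without DMSO replicate A these D7 ranges were −0.13 to −0.0245 and 0.114 to 0.346. A plate position shared by the D1 wells of all sets stays open too, and so does place in the set, since these genes shifted more at D1 in the chemical listed second in 6 of 6 sets. The lists drew on more calls of chemicals listed second, which may itself give part of that difference.

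The chemical listed second had more genes called than the first in 6 of 6 control sets at every level except D4 (5 of 6; in 4 to 6 sets without DMSO replicate A), and all 3 chemicals with many genes called at 6 or more levels were listed second. At D7 unequal depth is argued against by the mean total, higher in the second chemical in 3 of 6 sets, and totals were not compared in this way at the other levels. A chance order of the chemicals stays open: the exact two-sided sign-flip test at D7 was prompted by the same counts, and its p of 0.03125, the smallest that 6 sets can give, was 0.0625 without DMSO replicate A, where 1 set was equal. A difference common to the first and second chemicals, such as their place on a plate, may contribute: the direct differences at D7, second minus first, correlated across genes between control sets with a median Pearson r of 0.318 (0.169 to 0.427, 9089 genes that are not independent replicates). The correlation was above 0 in 15 of 15 pairs of sets at every level, with a median of 0.241 at D1, and against DMSO at D7 the median r between chemicals was 0.277 among those listed second and 0.0889 among those listed first. Place and chemistry are confounded in this design, so effects of the second chemicals stay open at all levels.

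Other groupings of the same libraries were refitted to see whether chance could give as many genes. For the counts over all levels, 40 groupings of the 24 libraries into 8 groups of 3 were used for each chemical, the real one included, and the real one gave the most in each (1 of 40). This is the smallest share that 40 groupings can give and was not adjusted over the 12 chemicals. The share lay under 0.05 for each count taken alone. This share alone excludes chance in none of the 12 chemicals. In fexofenadine, cis-nonachlordane and 3,4-dichlorophenyl isocyanate the highest other count also came close to the real one. Regrouping also treats the 24 libraries as exchangeable, which the labels do not establish. The real count and the highest other were 116 and 42 for 1(2H)-phthalazinone, 1081 and 26 for gabapentin, 80 and 21 for metribuzin-DA, 951 and 422 for 2-tert-butyl-4-methoxyphenol, 82 and 19 for hydrochlorothiazide, 659 and 29 for 4-chlorophenyl methyl sulfone, 93 and 42 for cetirizine, 214 and 20 for fipronil carboxamide, 58 and 55 for fexofenadine, 85 and 70 for cis-nonachlordane, 234 and 13 for metolachlor OA and 234 and 207 for 3,4-dichlorophenyl isocyanate. Among the DMSO sets they were 3259 and 307, again 1 of 40. At the fullest level the 6 libraries allow 10 splits, too few for a share under 0.05, and the real count and the highest other were 169 and 57, 1297 and 2, 82 and 5, 1728 and 382, 133 and 0, 1067 and 0, 61 and 0, 515 and 4, 40 and 12, 282 and 0, 151 and 8, and 512 and 0 in the order of the report, each real count again the highest (1 of 10).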
